A study of Rattus norvegicus with 9 samples.

How the data were processed

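Polyadenylated RNA from primary rat condylar cartilage progenitor cells was sequenced in 9 libraries: 3 of passage 3 cells (P3, control), 3 of passage 9 cells (P9) and 3 of passage 3 cells exposed to flow fluid shear stress (FFSS). The authors name HISAT2 2.0.5, featureCounts 1.5.0-p3 and the rat genome build Rnor_6.0, without their settings or the strandedness of the libraries. MicroRNA libraries of the same study are not part of this series and were not analysed here.

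The deposited values are FPKM, in a table of 34267 genes and 9 samples, with gene_length, the deposited length of each gene in bases, and other annotation columns. The unit was checked: value times length was a whole multiple of a single step per library for 100% of values, within a tolerance of 0.01 of a step. That step equalled the library's median-of-ratios size factor times the geometric mean of the library totals, with a largest deviation of 1.5e-09%, so the deposited FPKM already carry that scaling in place of plain library totals. The steps gave the fragments behind each value. The totals were 13264930 to 15323790 fragments per library. The precision at this depth is set by counting: 1 fragment on a gene of 1 kilobase is 0.0619 to 0.0733 FPKM, and 0 fragments still allow 3, or 0.186 to 0.220 FPKM at that length. These limits cover counting error only, since fragments without molecular identifiers are not independent molecules. Of the genes, 12299 were at 0 in every library. Gene symbols came from the deposited table; the supplied gene table for another rat build shared 0 gene identifiers with it, and its coordinates were not used.

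Genes with at least 1 FPKM in at least 3 libraries were kept (13059), and log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, as group means over all 9 libraries with an expression-dependent trend in the spread, 6 residual degrees of freedom and 2.93 prior degrees of freedom. The contrasts were P9 minus P3, FFSS minus P3 and P9 minus FFSS; the last tests whether the effects of the models differ. All tests were two-sided, and calls used a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. The design fixed before the data were examined named a count model for counts and this test for FPKM. Tables were prepared with Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9. With simulated changes in P9, 6.1% of 1.5-fold, 52% of 2-fold, 98% of 4-fold and 100% of 8-fold changes were recovered. Of 133 calls, 6 (4.5%) were unchanged genes. An unchanged simulated FFSS group gave 0 calls, no measure of false calls in the real one.

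The design fixed 33 gene lists, of which 27 had at least 5 tested members and were tested with camera (limma) at its preset correlation of 0.01, adjusted over lists within a contrast. Each was also tested with the correlation estimated from the data and with fry, a test of whether a list's genes move, on balance, in one direction. The lists were cell cycle arrest and senescence, mitosis, DNA replication, chromatin and lamina genes known to fall in senescence, p53 targets, secretory phenotype of senescent cells, NF-kB and Toll-like receptor signalling, interferon-stimulated genes, cartilage matrix and chondrogenic factors, hypertrophic and osteogenic genes, fibrillar collagens and fibrous matrix, matrix-degrading proteases, mesenchymal stem and progenitor markers, contractile and smooth muscle genes, YAP and SRF targets, immediate early and shear-responsive genes, NRF2 and antioxidant genes, unfolded protein and amino acid stress response, heat shock genes, cholesterol synthesis, hypoxia and glycolysis, oxidative phosphorylation, lysosome and autophagy, TGF-beta and BMP signalling, Wnt signalling, adipogenic genes, and markers of macrophages and leukocytes, endothelium, skeletal muscle, epithelium, glia and Schwann cells, erythroid cells, and synovial and tendon fibroblasts. For marker lists of other cell types, summed FPKM per library was computed over all listed genes.

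The genes named for each comparison followed a rule. Always named where measured were Cdkn1a, Cdkn2a, Cdkn2b, Lmnb1, Mki67, Sox9, Col2a1, Acan, Mmp3, Mmp13, Il6 and Tenm4. Added were up to 6 of the largest changes each way among called genes with a symbol, non-overlapping groups and at least 10 FPKM in 1 of the groups, and up to 4 members of each described list with the smallest adjusted p. For the shared response, the genes with the largest smaller change in both models were added. Genes named outside the rule are marked as chosen after their values were seen.

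For genes called in both models, observed counts and fold-change correlation were set beside 100 simulated draws of groups without effect that share the control libraries, since only 3 control libraries exist and could not be divided. Settings fixed before the data were examined were a pseudocount of 0.1, no filter, both together, a filter of at least 5 FPKM, a log2 fold of at least 1, scaling by library totals, the replicate number as a block, only the libraries compared, and leaving out each library in turn. Chosen after the data were seen were voom (limma) on the recovered fragments and equal FPKM totals. Of the settings fixed in advance, the negative-binomial tools were left out because the files hold FPKM and not counts, and the test of miR-708-5p sites because no genome sequence was supplied. Other splits of the libraries were refitted in the same way.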

Results

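The series measured polyadenylated RNA in primary cultures of cartilage progenitor cells from rat condylar cartilage, in 9 libraries that fell into 3 groups of 3. The control group, P3, held cells at passage 3. The P9 group held cells at passage 9, which the series uses as its model of replicative senescence, the arrest of division that follows repeated culture. The FFSS group held passage 3 cells exposed to flow fluid shear stress, the drag of moving liquid on a cell layer, which the series uses as its model of mechanically induced degeneration. The stated question was which mechanism the 2 models have in common. The libraries held 13264930 to 15323790 fragments assigned to genes, and 13059 of the 34267 annotated genes passed the filter of at least 1 FPKM (fragments scaled by gene length and library size) in at least 3 libraries. Values are given as mean FPKM ± SD with n = 3 libraries per group, and fold changes are log2 ratios of FPKM + 1, which understate the ratio of a gene near 1 FPKM. Nothing in the records says whether the libraries of a group came from separate animals or cultures, so each p measures only the spread between these libraries. Each value without a library leaves out that library alone, also where several are named.

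The groups separated by the largest components of variance, of which the first held 50.6% and the second 18.9%. The spread within a group differed. The SD of a gene's log2 value was 0.258 among P3 libraries, 0.338 among P9 libraries and 0.465 among FFSS libraries. FFSS replicate 1 stood apart from the other FFSS libraries on the side of P3. Across genes, its Pearson r was 0.915 with FFSS replicate 2 and 0.947 with FFSS replicate 3, against 0.942, 0.936 and 0.945 with P3 replicates 1 to 3. FFSS replicates 2 and 3 correlated at 0.969. Genes are not independent replicates, so these r values only describe the libraries. Mitochondrial transcripts took 2.12, 2.32 and 2.27% of fragments in the P3 libraries, 2.31, 2.56 and 2.33% in P9, and 3.44, 3.75 and 2.96% in FFSS. The 10 most abundant genes took 14.7 to 15.8% of fragments in P3, 12.4 to 13.1% in P9 and 10.9 to 11.0% in FFSS.

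**Figure D1:**
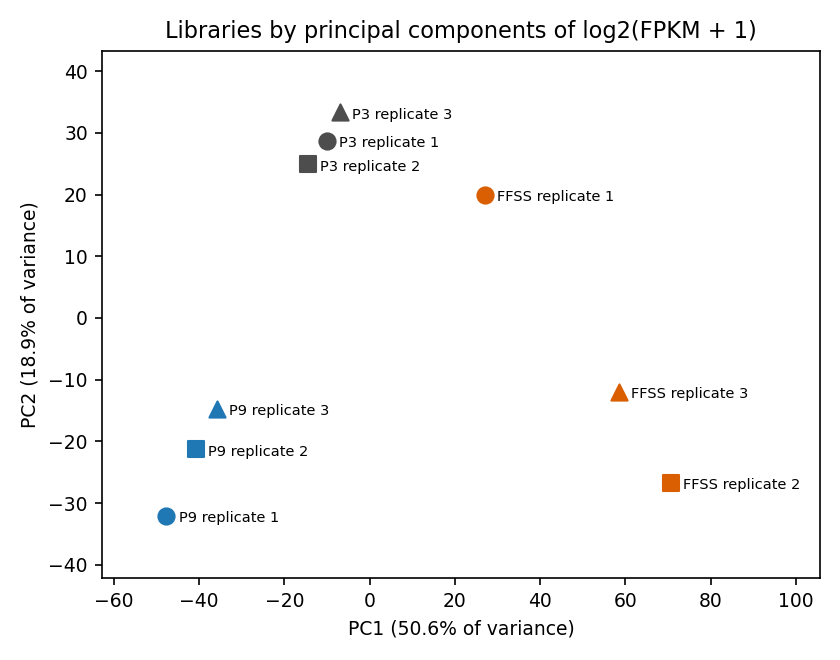
Each point is a library, placed by its scores on the first component (50.6% of variance, horizontal axis) and the second (18.9%, vertical axis) of log2(FPKM + 1), with colour for the group and shape for the replicate number. FFSS replicate 1, at 27.0 on the first component, lies between the P3 libraries (-14.5 to -7.0) and FFSS replicates 2 and 3 (70.6 and 58.4).

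In passage 9 cells, 9 of 18 contractile genes rose, 13 of 37 genes of the fibrous matrix fell while 4 rose, and 4 of 16 cartilage genes fell while Acan rose. Each set was called with the preset correlation of the test and not with an estimated correlation (adjusted p = 0.118, 0.351 and 0.147 in the same order). Acta2, the actin of smooth muscle and myofibroblasts, stood at 1565 ± 115 FPKM in P3 and 4362 ± 528 FPKM in P9 (SD, n = 3), a log2 fold change of 1.47 (adjusted p = 0.00163). Fmod, a small proteoglycan bound to collagen fibrils, fell from 1121 ± 133 to 72.4 ± 61.5 FPKM (log2 fold change -4.24, adjusted p = 0.000808). Acan, the core protein of the main cartilage proteoglycan, went the other way, from 128 ± 6.56 to 561 ± 56.4 FPKM (log2 fold change 2.12, adjusted p = 0.000288). Genes of mitosis did not fall at passage 9: limma called 0 of 29 (0 at an unadjusted p under 0.05, 0 with voom; 1 higher, Aurka, without FFSS replicate 1, adjusted p = 0.0388), and Mki67, a marker of dividing cells, stood at 13.2 ± 0.698 and 12.7 ± 0.44 FPKM (log2 fold change -0.05, adjusted p = 0.961).

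The largest rises at passage 9, among genes of at least 10 FPKM in P3 or P9 whose 3 libraries all lay above the 3 of P3, were those of Stmn2, Pln, Serpinb9, Osr1, Car3 and Car9. Stmn2, a microtubule-binding protein best known from neurons, stood at 0.7502 ± 0.569 FPKM in P3 and 33.2 ± 6.81 FPKM in P9 (log2 fold change 4.32, adjusted p = 6.03e-05). Pln, phospholamban, an inhibitor of the calcium pump of muscle, rose by 3.98 on the log2 scale to 78.8 ± 23.6 FPKM (adjusted p = 0.000406). Osr1, a transcription factor of mesenchymal development, rose from 5.18 ± 2.53 to 83.02 ± 15.2 FPKM (adjusted p = 0.000304). The log2 fold changes of Serpinb9, Car3 and Car9 were 3.95, 3.72 and 3.67, with adjusted p of 0.00082, 6.03e-05 and 6.03e-05. The largest falls were those of Abi3bp (-5.03), Pla2g2a (-4.31), Fmod, Aspnl1 (-3.75), Lum (-3.63) and Sfrp2 (-3.60). Abi3bp, a matrix protein, stood at 158 ± 25.4 FPKM in P3 and 4.32 ± 3.0 FPKM in P9 (adjusted p = 7.71e-05), and Lum, lumican, a relative of Fmod, at 32.3 ± 15.9 and 1.604 ± 1.13 FPKM (adjusted p = 0.000915). Aspnl1 stood at 66.8, 5.95 and 8.71 FPKM in P3 replicates 1 to 3. Its call (adjusted p = 0.0345) was lost without P3 replicate 1 (adjusted p = 0.0864) or 3 (0.0707), P9 replicate 1 (0.103), 2 (0.107) or 3 (0.0865), or FFSS replicate 3 (0.0515).

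Of 18 tested contractile and smooth muscle genes, 9 rose and none fell, with 13 higher when adjusted over the list alone. As a set they were higher than other genes (camera, adjusted p = 1.97e-09; adjusted p = 0.118 with an estimated correlation). Itga7, an integrin of muscle, rose from 1.497 ± 0.36 to 10.6 ± 1.69 FPKM (adjusted p = 0.00234). Vcl, vinculin of focal adhesions, rose from 110.3 ± 6.74 to 276 ± 80.7 FPKM (0.00319). Tpm1, a tropomyosin, rose from 237 ± 4.85 to 481 ± 44 FPKM (0.00357). Of 23 targets of the mechanically regulated factors YAP and SRF, 9 rose and none fell, with 12 higher adjusted over the list alone. The rises numbered 5 without P3 replicate 1 or 3 or P9 replicate 2 or 3. These targets together were higher, with adjusted p = 2.96e-06 and adjusted p = 0.147 with an estimated correlation. Ankrd1, a standard readout of YAP activity, rose from 0.418 ± 0.238 to 8.13 ± 1.39 FPKM (adjusted p = 0.000265). Tgfb2, a TGF-beta ligand, rose from 44.9 ± 3.13 to 137 ± 15.2 FPKM (0.00136), and Ajuba from 19.01 ± 2.94 to 43.6 ± 4.79 FPKM (0.00198). Acta2, Tagln, Cnn1 and Vcl belong to both lists. Skeletal muscle markers (3 tested) summed to 13.9 ± 4.98 FPKM in P3 and 48.3 ± 3.45 in P9 (SD, n = 3). Most of the rise was Acta1, skeletal actin, at 7.96 ± 5.67 and 38.7 ± 3.73 FPKM.

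Of 16 cartilage matrix and chondrogenic genes, Col11a1, Sox6, Fmod and Cilp2 fell and Acan rose, with 6 lower and 1 higher adjusted over the list alone. The cartilage set was lower, with adjusted p = 0.00304 and adjusted p = 0.147 with an estimated correlation. Cilp2, named after its values were seen, lost its call without P3 replicate 1 (adjusted p = 0.121), 2 (0.118) or 3 (0.108), P9 replicate 1 (0.135) or 2 (0.14), or FFSS replicate 3 (0.0624). The cartilage genes that fell numbered 7 without FFSS replicate 1. Col11a1, a minor fibrillar collagen of cartilage, went from 857 ± 55.6 to 234 ± 63.7 FPKM (adjusted p = 0.000524) and Sox6, a partner of Sox9, from 5.53 ± 0.538 to 1.28 ± 0.382 FPKM (0.000731). Sox9, the main chondrogenic transcription factor, stood at 4.52 ± 0.403 and 6.46 ± 1.49 FPKM (log2 fold change 0.42, adjusted p = 0.239). Col2a1, the main collagen of cartilage, was below the filter, at 0.703 to 1.06 FPKM in the P3 libraries and 0 to 0.191 FPKM in P9, and was not tested. Of 37 fibrillar collagens and fibrous matrix genes, 13 fell and 4 rose, with 15 lower and 7 higher adjusted over the list alone. The falls numbered 7 without P3 replicate 1 or 3, and 8 without P3 replicate 2 or P9 replicate 2, and the rises 1 without P3 replicate 1 or 3, 2 without P9 replicate 2, and 7 without FFSS replicate 1. The fibrous matrix set was lower, with adjusted p = 0.0122 and adjusted p = 0.351 with an estimated correlation. Col12a1 went from 1062 ± 18.3 to 153 ± 36.4 FPKM and Thbs2 from 427 ± 30.8 to 46.4 ± 12.9 FPKM (adjusted p = 6.22e-05 and 6.33e-05). Lox, the crosslinking enzyme of collagen, went from 1011 ± 56.9 to 353 ± 52.2 FPKM (0.000313). Postn, Fbn1, Fbln2 and Tnc rose, the last 3 named after their values were seen. Fbn1 lost its call without P3 replicate 1 (adjusted p = 0.0524) or 3 (0.0601). Fbln2 lost it without P3 replicate 1 (adjusted p = 0.058) or 3 (0.071), or P9 replicate 2 (0.0645). Tnc lost it without P3 replicate 1 (adjusted p = 0.131) or 3 (0.123), P9 replicate 1 (0.122), 2 (0.111) or 3 (0.0836), or FFSS replicate 3 (0.0681). Postn, periostin, reached 1569 ± 282 FPKM from 298 ± 31.2 (adjusted p = 0.000447). Of 12 hypertrophic and osteogenic genes, Pth1r, Runx3, Sp7, Runx2 and Dlx3 fell and none rose, with 6 lower and 3 higher adjusted over the list alone. The osteogenic set was lower, with adjusted p = 0.0139 and adjusted p = 0.351 with an estimated correlation, and it was not called without a filter or with a filter of at least 5 FPKM. The osteogenic genes that fell numbered 3 without P3 replicate 1, 2 or 3 or P9 replicate 1 or 2, and those that rose 1 without FFSS replicate 1 or 2. Sp7, the osteoblast factor osterix, went from 16.5 ± 2.0 to 1.18 ± 1.39 FPKM (adjusted p = 0.00299). Dlx3, named after its values were seen, lost its call without P3 replicate 1 (adjusted p = 0.0992), 2 (0.113) or 3 (0.0987), or P9 replicate 1 (0.0992) or 2 (0.117). Runx2 (adjusted p = 0.0293) lost its call without P3 replicate 1 (adjusted p = 0.114), 2 (0.0987) or 3 (0.0871), P9 replicate 1 (0.059), 2 (0.0967) or 3 (0.0877), or FFSS replicate 3 (0.0514). Synovial and tendon fibroblast markers summed to 1538 ± 69.0 FPKM in P3 and 453 ± 95.4 in P9 (SD, n = 3). Most of the fall was Fmod, a cartilage gene too.

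Genes of the unfolded protein and amino acid stress response were lower at passage 9: 7 of 30 fell and none rose, and 18 were lower adjusted over the list alone. The falls numbered 4 without P3 replicate 1 or 2 or P9 replicate 2 or 3, 12 without FFSS replicate 2, and 18 without FFSS replicate 1. The set passed with the preset correlation (adjusted p = 8.09e-11) and, alone among the lists of this comparison, with an estimated correlation (adjusted p = 0.0427). Slc7a5 and Slc3a2, the chains of a transporter of large amino acids, went from 124 ± 3.49 to 50.01 ± 3.62 and from 215 ± 8.56 to 136 ± 1.23 FPKM (adjusted p = 0.000221 and 0.00263). Trib3, a target of the stress factor Atf4, and Hspa5, the chaperone BiP, had log2 fold changes of -1.51 and -0.78 (adjusted p = 0.00207 and 0.00373).

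Of 36 genes of the senescent secretory phenotype, 6 fell and Nrg1 alone rose, with 8 lower and 1 higher adjusted over the list alone. The secretory set was called lower with adjusted p = 0.0366 and adjusted p = 0.147 with an estimated correlation. Nrg1, a growth factor named after its values were seen, lost its call without P3 replicate 1 (adjusted p = 0.0881) or 3 (0.0545), P9 replicate 1 (0.107), 2 (0.106) or 3 (0.0726), or FFSS replicate 3 (0.0565). The secretory genes that rose numbered 0 without P3 replicate 1 or 3, P9 replicate 1, 2 or 3 or FFSS replicate 3, and 3 without FFSS replicate 1. Angptl4 went from 11.5 ± 0.747 to 1.59 ± 0.477 FPKM and Igfbp4 from 40.6 ± 11.5 to 5.55 ± 2.7 FPKM (adjusted p = 0.000411 and 0.000899). The chemokine gene Cxcl1 went from 28.6 ± 3.56 to 5.34 ± 2.7 FPKM (0.00176). Il6 stood at 1.396 ± 0.536 and 2.93 ± 1.05 FPKM (log2 fold change 0.70, adjusted p = 0.13). Of 25 genes of NF-kB and Toll-like receptor signalling, Tnfaip2, Relb and Bcl3 fell and none rose, with the same counts adjusted over the list alone. The rises numbered 1 without FFSS replicate 1. The NF-kB set was lower, with adjusted p = 0.00949 and adjusted p = 0.147 with an estimated correlation. The log2 fold changes of Tnfaip2 and Relb were -0.82 and -0.88. Bcl3 (adjusted p = 0.039) lost its call without P3 replicate 1 (adjusted p = 0.147) or 3 (0.155), P9 replicate 1 (0.101), 2 (0.119) or 3 (0.0812), or FFSS replicate 3 (0.0578). Of 27 matrix-degrading proteases, Adamts2, Mmp23, Mmp3, Ctsd and Fap fell and Htra1 rose, with 10 lower and 2 higher adjusted over the list alone. The protease set was lower, with adjusted p = 0.0259, 0.0597 without P9 replicate 3, and adjusted p = 0.147 with an estimated correlation. Mmp3, stromelysin, went from 11.3 ± 6.89 to 0.815 ± 0.2 FPKM (adjusted p = 0.00326). Mmp13, collagenase of hypertrophic cartilage, stood at 0.392 ± 0.317 and 0.117 ± 0.0434 FPKM (adjusted p = 0.769). Htra1 lost its call without P3 replicate 1 (adjusted p = 0.0524) or 3 (0.0505), or P9 replicate 2 (0.0514). Ctsd lost its call without P3 replicate 1 (adjusted p = 0.0796) or 3 (0.0781). Fap lost its call without P3 replicate 1 (adjusted p = 0.176) or 3 (0.182), P9 replicate 1 (0.102), 2 (0.132) or 3 (0.13), or FFSS replicate 3 (0.0747). Fap and Ctsd were named here after their values were seen. The proteases that fell numbered 3 without P3 replicate 1 or 3, 9 without FFSS replicate 2, and 10 without FFSS replicate 1, and those that rose 0 without P3 replicate 1 or 3 or P9 replicate 2, and 3 without FFSS replicate 1. Of 36 lysosome and autophagy genes, Ctsz, Ctsd, Man2b1, Psap and Lamp1 fell and none rose, with 7 lower adjusted over the list alone. The lysosome set was lower, with adjusted p = 0.0366, 0.0920 without P9 replicate 3, and adjusted p = 0.250 with an estimated correlation. The lysosome genes that fell numbered 1 without P3 replicate 1 or 3 or P9 replicate 2, 2 without P3 replicate 2 or P9 replicate 3, 3 without P9 replicate 1 or FFSS replicate 3, and 8 without FFSS replicate 1. Ctsz lost its call without P9 replicate 2 (adjusted p = 0.0506). Man2b1 lost its call without P3 replicate 1 (adjusted p = 0.117), 2 (0.0925) or 3 (0.119), or P9 replicate 2 (0.0963) or 3 (0.0875). Psap lost its call without P3 replicate 1 (adjusted p = 0.169), 2 (0.121) or 3 (0.157), P9 replicate 1 (0.0716), 2 (0.118) or 3 (0.124), or FFSS replicate 3 (0.0761). Lamp1 lost its call without P3 replicate 1 (adjusted p = 0.162), 2 (0.0818) or 3 (0.178), P9 replicate 1 (0.109), 2 (0.109) or 3 (0.0965), or FFSS replicate 3 (0.0759). With a filter of at least 5 FPKM, the NF-kB set was still called and the secretory, protease and lysosome sets were not. The secretory set was also not called with only the P3 and P9 libraries, nor the lysosome set with library totals. Leukocyte markers summed to 2.34 ± 0.470 FPKM in P3 and 3.02 ± 0.350 FPKM in P9 (SD, n = 3).

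Among cell cycle genes, Cdkn2a, which encodes the senescence-linked inhibitor p16 (Rnor_6.0 chromosome 5, 107823330 to 107841175, minus strand), stood at 6.88 ± 0.799 FPKM in P3 and 12.98 ± 0.692 FPKM in P9 (log2 fold change 0.83, adjusted p = 0.0337). That call was lost without each P3 or P9 library (adjusted p = 0.0641 to 0.13). It was kept without each FFSS library (lowest 0.00155). Cdkn1a, which encodes p21, stood at 80.2 ± 16.1 and 135 ± 18.3 FPKM (log2 fold change 0.75, adjusted p = 0.369) and passed without FFSS replicate 1 (adjusted p = 0.0284). Cdkn2b and Lmnb1, the lamin that is commonly lost in senescence, did not pass (log2 fold changes -0.29 and 0.34, adjusted p = 0.343 and 0.744). Of 22 p53 targets, Pmaip1, Fas, Zmat3 and Eda2r rose and none fell, with 5 higher adjusted over the list alone. The p53 target set was higher, with adjusted p = 0.0292 and adjusted p = 0.690 with an estimated correlation, and it was not called with a filter of at least 5 FPKM or with fry. The p53 targets that rose numbered 2 without P3 replicate 1 or 3 or P9 replicate 2, and 11 without FFSS replicate 1, and those that fell 2 without FFSS replicate 1. Pmaip1, the pro-apoptotic Noxa, went from 10.8 ± 3.68 to 44.9 ± 11.2 FPKM (adjusted p = 0.00366). Fas, a death receptor, went from 4.08 ± 0.469 to 9.59 ± 1.33 FPKM (0.00623). Zmat3 lost its call without P3 replicate 1 (adjusted p = 0.0785) or 3 (0.0764), or P9 replicate 2 (0.0694) or 3 (0.0513). Eda2r lost its call without P3 replicate 1 (adjusted p = 0.0735), 2 (0.0579) or 3 (0.0779), or P9 replicate 1 (0.0771) or 2 (0.082). Limma called 0 of 30 DNA replication genes, over all genes or adjusted over the list alone (5 at an unadjusted p under 0.05, 1 with voom). The set was nonetheless called higher (adjusted p = 0.0456; adjusted p = 0.808 with an estimated correlation). That call was lost without P3 replicate 1 (0.0924), P3 replicate 3 (0.0560), P9 replicate 1 (0.0754) or P9 replicate 3 (0.0825). It was also lost with a filter of at least 5 FPKM, with a pseudocount of 0.1, with library totals and with fry. The replication genes that rose numbered 2 without FFSS replicate 1 or 2. The 29 mitosis genes had a median log2 fold change of 0.25 (set adjusted p = 0.0979; 0.0166, higher, without FFSS replicate 1 or without FFSS replicate 2).

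In all, limma called 704 genes higher and 580 lower at passage 9 (1284 of 13059, 9.8%), and 40.1% of genes had groups that did not overlap, against 10% by chance. The count was 619 without P3 replicate 1, 841 without P3 replicate 2, 626 without P3 replicate 3, 696 without P9 replicate 2 and 2230 without FFSS replicate 1.

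**Figure D2:**
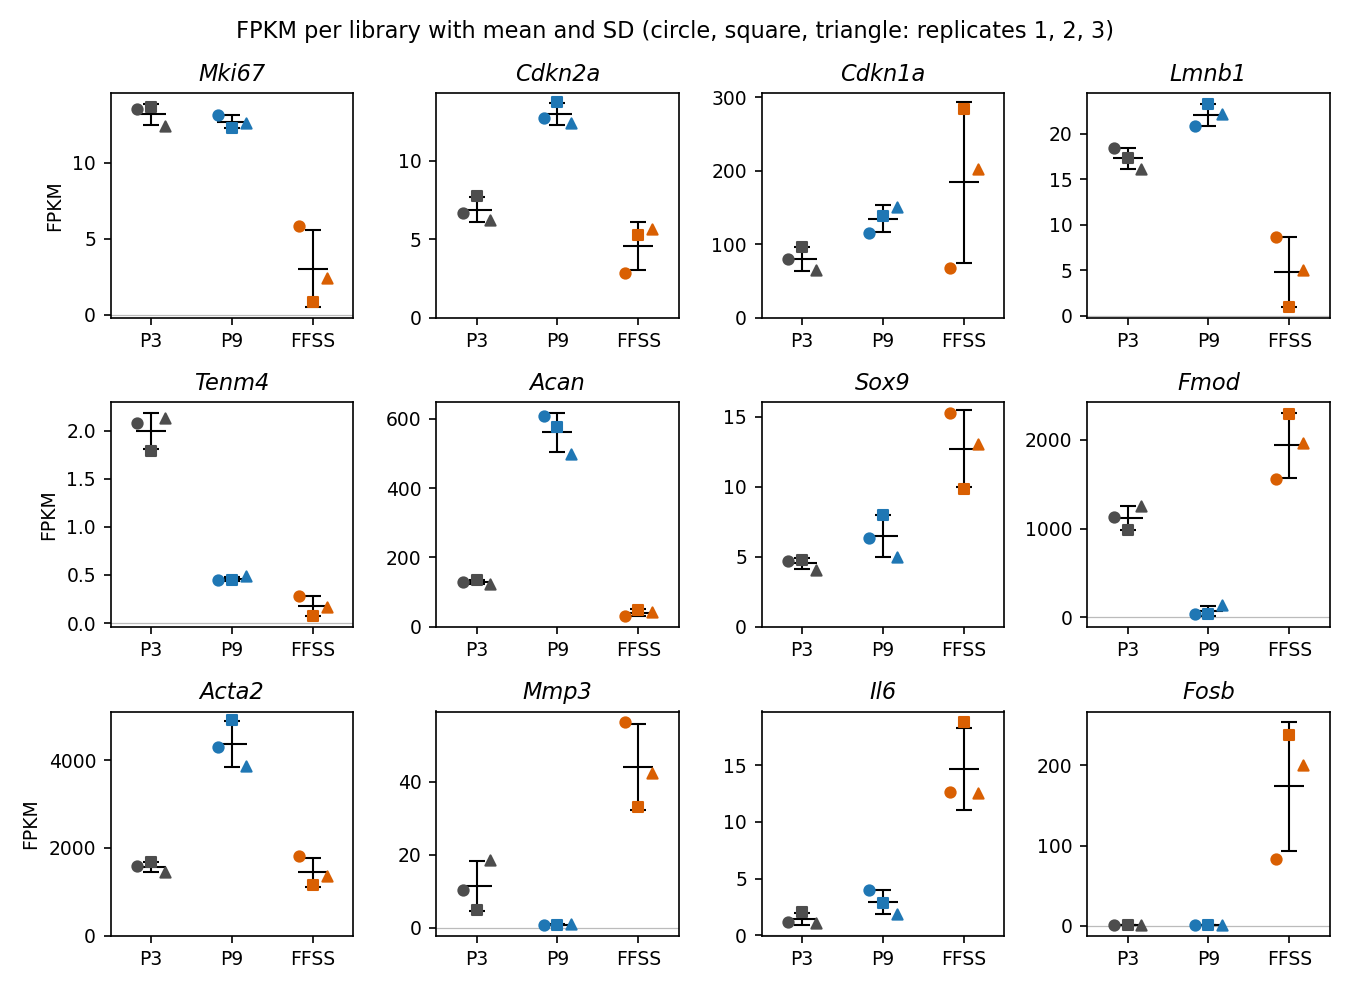
Each panel shows a gene's FPKM (vertical axis, linear) in the 3 libraries of each group, with the group mean and SD as black bars and circles, squares and triangles for replicates 1 to 3. Mki67 was at 13.2 ± 0.698 FPKM in P3, 12.7 ± 0.44 in P9 and 3.05 ± 2.56 in FFSS, while Acan was at 128 ± 6.56, 561 ± 56.4 and 40.2 ± 9.8 FPKM (SD, n = 3).

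Under flow shear stress, 23 of 32 immediate early genes rose while 2 fell, 22 of 25 NF-kB genes rose, and the 29 tested mitosis genes fell. With an estimated correlation the NF-kB set was called (adjusted p = 0.00611), and the immediate early and mitosis sets were not (adjusted p = 0.197 and 0.294). Fosb and Fos, subunits of the transcription factor AP-1, rose from 0.509 ± 0.0956 to 174 ± 80.3 FPKM and from 3.57 ± 0.24 to 234 ± 74.6 FPKM (SD, n = 3). Their log2 fold changes were 6.73 and 5.63 (adjusted p = 9.57e-06 and 8.8e-06). Ccl2, a chemokine that draws monocytes, rose from 28.4 ± 6.86 to 1029 ± 193 FPKM (log2 fold change 5.14, adjusted p = 8.8e-06). Mki67 fell from 13.2 ± 0.698 to 3.05 ± 2.56 FPKM (log2 fold change -2.01, adjusted p = 0.00818). The mitochondrial fragment share was higher in each FFSS library (2.96 to 3.75%) than in any P3 library (2.12 to 2.32%).

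Of 32 immediate early and shear-responsive genes, 23 rose and Piezo1 and Trpv2, both ion channels, fell, with 24 higher and 2 lower adjusted over the list alone. The set was higher (adjusted p = 2.36e-13; adjusted p = 0.197 with an estimated correlation). The orphan nuclear receptors Nr4a1 and Nr4a2 were among its clearest members (log2 fold changes 3.61 and 1.92, adjusted p = 9.57e-06 and 0.000109). Piezo1 and Trpv2 were named here after their values were seen. Piezo1 lost its call without P3 replicate 1 (adjusted p = 0.0568). Trpv2 lost its call without P3 replicate 1 (adjusted p = 0.124), 2 (0.123) or 3 (0.109), P9 replicate 1 (0.0595), 2 (0.0727) or 3 (0.0648), or FFSS replicate 2 (0.0602) or 3 (0.0956). The falls numbered 0 without P3 replicate 1, and 1 without P3 replicate 2 or 3, P9 replicate 1, 2 or 3 or FFSS replicate 2 or 3. The summed FPKM of the list was 771 ± 32.9 in P3 and 1758, 4490 and 3491 in FFSS replicates 1 to 3. Of 25 genes of NF-kB and Toll-like receptor signalling, 22 rose and none fell, over all genes and adjusted over the list alone. The set passed with the preset correlation (adjusted p = 5.1e-15) and with an estimated correlation (adjusted p = 0.00611). Nfkbia and Tnfaip3, inhibitors that NF-kB itself induces, went from 8.71 ± 0.945 to 78.8 ± 5.14 and from 1.82 ± 0.0402 to 15.3 ± 1.16 FPKM (adjusted p = 4.57e-06 and 9.57e-06). Nfkbiz, a co-activator, went from 2.501 ± 0.593 to 50 ± 5.46 FPKM (4.57e-06). Cd14, a co-receptor of Toll-like receptors, went from 9.14 ± 0.62 to 67.2 ± 27.2 FPKM (0.00062). Leukocyte markers summed to 2.34 ± 0.470 FPKM in P3 and 10.4 ± 6.09 FPKM in FFSS (SD, n = 3). Cd68 was the sole tested member, at 2.29 ± 0.269 FPKM in FFSS.

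Of 36 genes of the senescent secretory phenotype, 18 rose and Igfbp4 and Inhba fell, with 22 higher and 4 lower adjusted over the list alone (set adjusted p = 1.03e-05; adjusted p = 0.0232 with an estimated correlation). Il6 rose from 1.396 ± 0.536 to 14.7 ± 3.62 FPKM (adjusted p = 0.000549). Cxcl1 rose from 28.6 ± 3.56 to 457 ± 97.8 FPKM and Angptl4 from 11.5 ± 0.747 to 149 ± 43.1 FPKM (0.000139 and 3.72e-05). Of 27 matrix-degrading proteases, 11 rose and Adamts1, Adamts2 and Adamts12 fell, with 12 higher and 3 lower adjusted over the list alone. Proteases as a set were higher, with adjusted p = 0.00387 and adjusted p = 0.122 with an estimated correlation. Mmp2, a gelatinase, went from 658 ± 53.2 to 1729 ± 241 FPKM (adjusted p = 0.000691). Mmp3 rose from 11.3 ± 6.89 to 43.9 ± 11.8 FPKM and Mmp13 from 0.392 ± 0.317 to 12.1 ± 7.44 FPKM (0.00862 and 0.00376). Of 30 hypoxia and glycolysis genes, 12 rose and Pfkp fell, with 15 higher and 1 lower adjusted over the list alone. Hypoxia and glycolysis genes as a set were higher, with adjusted p = 5.89e-05 and adjusted p = 0.0232 with an estimated correlation. Pfkfb3, an activator of glycolysis, Car9, a carbonic anhydrase induced by hypoxia, and Ldha, lactate dehydrogenase, had log2 fold changes of 1.26, 1.86 and 0.90 (adjusted p = 0.000747, 0.00105 and 0.00174). Inhba, Adamts2, Adamts12 and Pfkp were named here after their values were seen. Adamts12 lost its call without P3 replicate 1 (adjusted p = 0.0925), 2 (0.104) or 3 (0.0601), P9 replicate 2 (0.0502), or FFSS replicate 3 (0.0562). Pfkp lost its call without P3 replicate 1 (adjusted p = 0.125), 2 (0.0885) or 3 (0.117), P9 replicate 1 (0.0547), 2 (0.0612) or 3 (0.0552), or FFSS replicate 2 (0.0999) or 3 (0.122). The proteases that rose numbered 4 without P3 replicate 1 or 2, and 5 without FFSS replicate 3. The hypoxia and glycolysis genes that rose numbered 5 without P3 replicate 1 or 2, and 6 without P3 replicate 3, and those that fell 0 without P3 replicate 1, 2 or 3, P9 replicate 1, 2 or 3 or FFSS replicate 2 or 3, and 2 without FFSS replicate 1.

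Of 21 interferon-stimulated genes, 8 rose and none fell, with 11 higher adjusted over the list alone. As a set they were higher (adjusted p = 0.000166, 0.294 with an estimated correlation), but not called with a filter of at least 5 FPKM. Without FFSS replicate 1, the set's adjusted p was 0.0477 and 2 genes fell. The list summed to 183 FPKM in P3 and 563, 244 and 338 in FFSS replicates 1 to 3. Ifi44, Tap1 of antigen processing and the factor Irf1 had log2 fold changes of 1.59, 1.06 and 1.91 (adjusted p = 0.000681, 0.00106 and 0.00216). Of 22 p53 targets, 8 rose and Rrm2b, named after its values were seen, fell, with the same counts adjusted over the list alone. Targets of p53 as a set were higher, with adjusted p = 0.000391 and adjusted p = 0.441 with an estimated correlation, and not called with fry. The p53 targets that rose numbered 3 without P3 replicate 1 or 2 or FFSS replicate 3, 4 without P3 replicate 3, 5 without FFSS replicate 2, and 17 without FFSS replicate 1, and those that fell 0 without P3 replicate 1, 2 or 3, P9 replicate 1 or 2 or FFSS replicate 2 or 3. Rrm2b lost its call without P3 replicate 1 (adjusted p = 0.148), 2 (0.0596) or 3 (0.111), P9 replicate 1 (0.055) or 2 (0.061), or FFSS replicate 2 (0.103) or 3 (0.0956). Btg2, an inhibitor of proliferation, rose from 8.08 ± 0.4 to 154 ± 112 FPKM and Plk2 from 11.7 ± 0.74 to 46.1 ± 21.3 FPKM (adjusted p = 0.00433 and 0.0071). Of 36 lysosome and autophagy genes, 10 rose and none fell, over all genes and adjusted over the list alone. Hexa, a lysosomal hexosaminidase, and Sqstm1, the autophagy receptor p62, had log2 fold changes of 0.69 and 0.53. The lysosome genes that rose numbered 3 without P3 replicate 1 or 2, 4 without P3 replicate 3 or FFSS replicate 2 or 3, 6 without P9 replicate 2, and 17 without FFSS replicate 1. Lysosome genes as a set were higher, with adjusted p = 0.00105 and adjusted p = 0.145 with an estimated correlation. Of 26 NRF2 and antioxidant genes, 7 rose and none fell, over all genes and adjusted over the list alone. Gpx3, a secreted glutathione peroxidase, rose from 617 ± 52.8 to 2898 ± 629 FPKM. The antioxidant genes that fell numbered 2 without FFSS replicate 1. Antioxidant genes as a set were higher, with adjusted p = 0.0014 and adjusted p = 0.210 with an estimated correlation. Of 22 cholesterol synthesis genes, Stard4 and Ebp rose, over all genes and adjusted over the list alone (log2 fold changes 1.41 and 0.74). Cholesterol genes as a set were higher, with adjusted p = 0.0334 and adjusted p = 0.778 with an estimated correlation. That set call was lost without FFSS replicate 1 (adjusted p = 0.0648), FFSS replicate 2 (0.0600) or P3 replicate 2 (0.435), and also without a filter and with fry. The cholesterol genes that rose numbered 1 without P3 replicate 1 or 2, and 5 without FFSS replicate 1. Ebp lost its call without P3 replicate 1 (adjusted p = 0.0547) or 2 (0.066).

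All 29 tested mitosis genes fell, over all genes and adjusted over the list alone, and all 29 did so without FFSS replicate 1. The set was lower with the preset correlation (adjusted p = 1.97e-15), although adjusted p = 0.294 with an estimated correlation, since the members move together (estimated correlation 0.901). Cenpe, a kinetochore motor, went from 7.98 ± 1.13 to 1.93 ± 0.456 FPKM and the kinase gene Aurka from 9.42 ± 1.3 to 2.05 ± 1.13 FPKM (adjusted p = 0.000651 and 0.0019). Anln, anillin of the cleavage furrow, went from 45.3 ± 6.03 to 9.12 ± 5.0 FPKM and Cenpf from 7.13 ± 1.09 to 1.27 ± 1.07 FPKM (0.00208 and 0.00421). The summed FPKM of the list was 476 ± 34.97 in P3 (SD, n = 3) and 216, 44.5 and 104 in FFSS replicates 1 to 3. Of 30 DNA replication genes, 9 fell and none rose, with 17 lower adjusted over the list alone. The replication genes that fell numbered 2 without P3 replicate 1, 2 or 3 or FFSS replicate 3, 5 without P9 replicate 2 or 3, and 24 without FFSS replicate 1. Replication genes as a set were lower, with adjusted p = 1.03e-05 and adjusted p = 0.443 with an estimated correlation, and not called with fry. Ccne1, cyclin E, and Rrm1, a subunit of ribonucleotide reductase, had log2 fold changes of -0.86 and -1.36 (adjusted p = 0.00516 and 0.0117). Of 12 chromatin and lamina genes known to fall in senescence, 9 fell and none rose, over all genes and adjusted over the list alone. The chromatin and lamina genes that fell numbered 4 without P3 replicate 1, 2 or 3, and 5 without FFSS replicate 3. Chromatin and lamina genes as a set were lower, with adjusted p = 0.000538 and adjusted p = 0.294 with an estimated correlation. Smc2 and Ncapg, parts of condensin, had log2 fold changes of -1.27 and -2.10 (adjusted p = 0.00134 and 0.0033). Lmnb1 fell from 17.3 ± 1.15 to 4.83 ± 3.87 FPKM (adjusted p = 0.0218) and lost its call without P3 replicate 1 (adjusted p = 0.073), 2 (0.0687) or 3 (0.0602).

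Cdkn1a stood at 80.2 ± 16.1 FPKM in P3 and 184 ± 109 FPKM in FFSS (log2 fold change 0.98, adjusted p = 0.144), and passed without FFSS replicate 1 (adjusted p = 0.000885). It was at 67.2 FPKM in FFSS replicate 1 and at 284 and 202 FPKM in the others. Cdkn2a stood at 4.59 ± 1.52 FPKM in FFSS (log2 fold change -0.53, adjusted p = 0.0918). Cdkn2b, which encodes p15, fell from 18.8 ± 1.37 to 10.5 ± 2.56 FPKM (adjusted p = 0.0117), a call lost without P3 replicate 2 (adjusted p = 0.0508). Sox9 rose from 4.52 ± 0.403 to 12.7 ± 2.74 FPKM (log2 fold change 1.29, adjusted p = 0.00338). Acan fell from 128 ± 6.56 to 40.2 ± 9.8 FPKM (log2 fold change -1.68, adjusted p = 0.000827). Col2a1 was at 0.0297 to 0.378 FPKM in the FFSS libraries and was not tested. The other large rises were those of Slpi, Serpina3n and Lcn2, secreted proteins of the acute phase and of mucosal defence, which also differed widely between FFSS libraries. Slpi stood at 1353, 25.1 and 407 FPKM in FFSS replicates 1 to 3, Lcn2 at 539, 1.78 and 184 FPKM, and Serpina3n at 53.5, 510.1 and 327 FPKM. Their P3 means were 2.21 ± 1.77, 0.281 ± 0.15 and 1.73 ± 1.18 FPKM (adjusted p = 0.00784, 0.0324 and 0.00116). Lcn2 lost its call without P3 replicate 1 (adjusted p = 0.0863), 2 (0.0909) or 3 (0.0889), P9 replicate 2 (0.0521) or 3 (0.0507), or FFSS replicate 3 (0.11). Among the largest falls were those of Dynap (-3.61), Dio3, an enzyme that inactivates thyroid hormone (-3.44), Plekha7 of adherens junctions (-3.14), the smooth muscle actin gene Actg2 (-2.71) and Pkp1 of desmosomes (-2.61, adjusted p = 9.57e-06).

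Limma called 1483 genes higher and 1362 lower under shear (2845 of 13059, 21.8%), and 42.4% of genes had groups that did not overlap, against 10% by chance. The count was 1182 without P3 replicate 1, 1307 without P3 replicate 2, 1473 without P3 replicate 3, 1496 without FFSS replicate 3 and 5131 without FFSS replicate 1. With every library scaled to the same summed FPKM, which put the median of all genes at -0.116 on the log2 scale, 1121 genes were higher and 1958 lower.

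**Figure D3:**
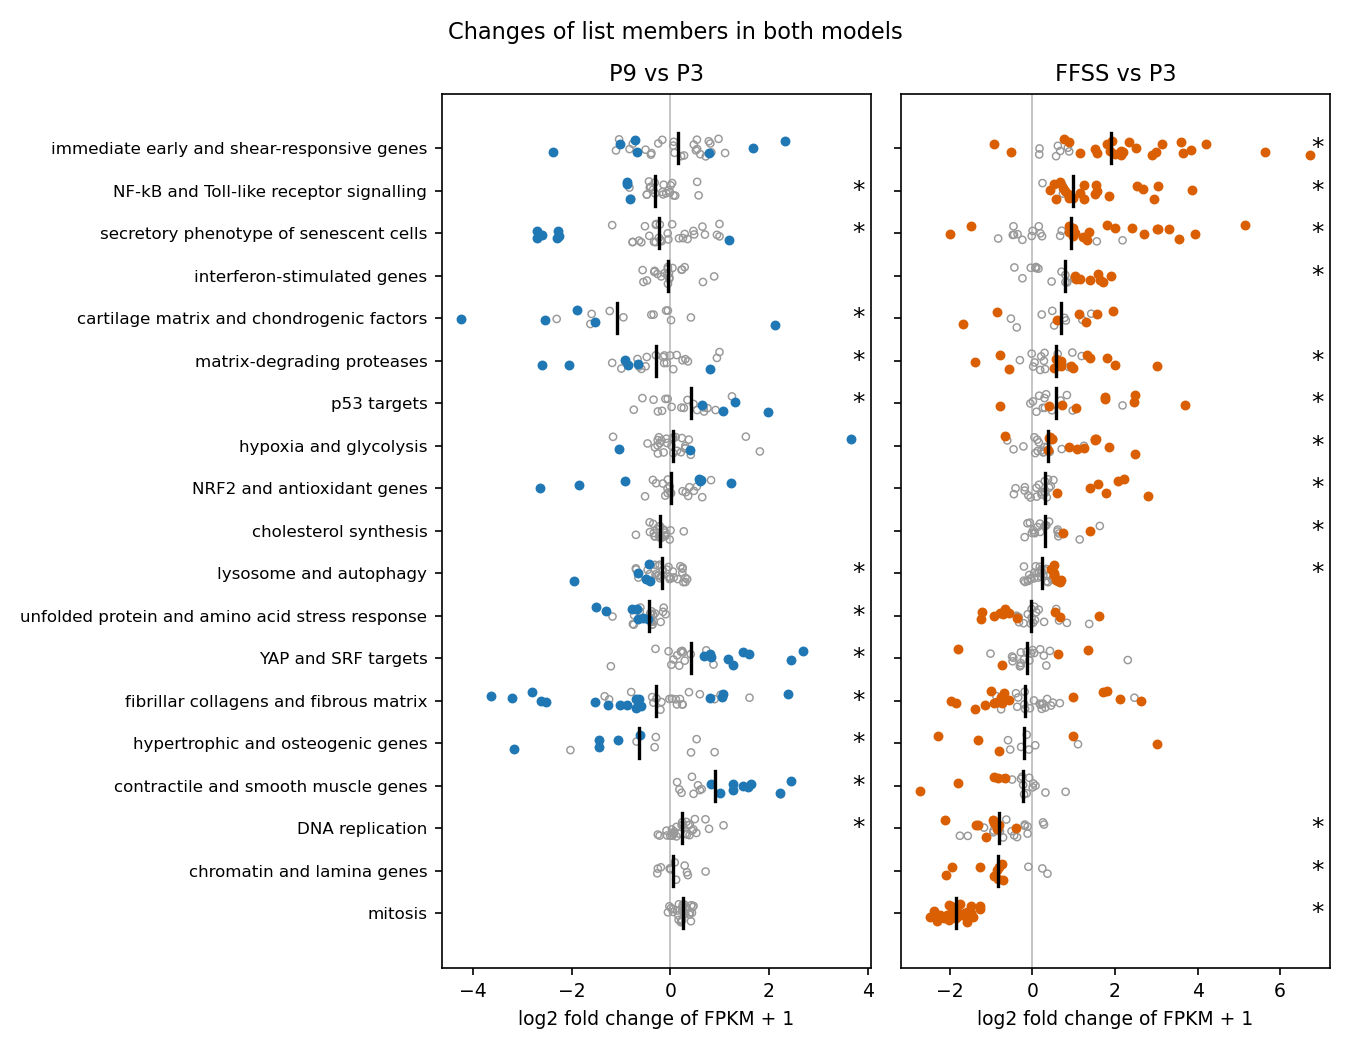
Each point is a tested member of a list named on the vertical axis, placed by its log2 fold change of FPKM + 1 (horizontal axis) in P9 vs P3 (left) and FFSS vs P3 (right). Filled points passed at adjusted p under 0.05, black bars are medians, and an asterisk marks a set that camera called with its preset correlation. The mitosis median is 0.25 on the left and -1.84 on the right.

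The models were then compared with each other, which tests for each gene whether its changes against P3 differed. Mitosis genes were higher in P9 than in FFSS at all 29 members, with a median log2 difference of 2.07 (set adjusted p = 4.77e-14; adjusted p = 0.218 with an estimated correlation). NF-kB and Toll-like receptor genes were lower in P9 at 21 of 25 members, 23 adjusted over the list alone, and higher at none (set adjusted p = 4.77e-14; adjusted p = 0.00739 with an estimated correlation). Genes of the senescent secretory phenotype were lower in P9 at 19 and higher at 4 of 36 members, 22 and 4 adjusted over the list alone (set adjusted p = 4.85e-07; adjusted p = 0.0156 with an estimated correlation). The secretory genes higher in P9 numbered 2 without P9 replicate 1 or FFSS replicate 3. Nfkbiz differed by -4.35 on the log2 scale, Ccl2 by -5.90, Angptl4 by -5.83 and Cenpe by 1.63 (adjusted p = 1.3e-06, 2.04e-06, 1.3e-06 and 0.000175).

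Immediate early genes were lower in P9 at 24 of 32 members and higher at none, 25 adjusted over the list alone (set adjusted p = 2.15e-11; adjusted p = 0.130 with an estimated correlation), with Nr4a1 at -4.33 (adjusted p = 2.31e-06). The immediate early genes higher in P9 numbered 1 without FFSS replicate 1. Contractile genes were higher in P9 at 13 of 18 members, 15 adjusted over the list alone (set adjusted p = 6.26e-08; adjusted p = 0.0707 with an estimated correlation). YAP and SRF targets were higher at 13 and lower at 2, Dlc1 and Ptx3, of 23 members, 14 and 2 adjusted over the list alone (set adjusted p = 0.000243; adjusted p = 0.125 with an estimated correlation). Lmod1, leiomodin of smooth muscle, and Vcl had log2 differences of 2.39 and 1.77 (adjusted p = 0.000182 and 0.000257). Cartilage genes were lower in P9 at 11 of 16 members, 12 adjusted over the list alone, with Acan the sole member that was higher (set adjusted p = 5.83e-05; adjusted p = 0.0707 with an estimated correlation). Acan stood 3.80 higher on the log2 scale and Sox6 at -2.12 (adjusted p = 3.81e-06 and 5.01e-05). Proteases were lower in P9 at 11 and higher at 2, Adamts1 and Adamts12, of 27 members, 13 and 2 adjusted over the list alone. Proteases as a set were lower in P9, with adjusted p = 0.000154 and adjusted p = 0.0531 with an estimated correlation. Dlc1, Ptx3, Adamts1 and Adamts12 were named here after their values were seen. Ptx3 lost its call without P3 replicate 1 (adjusted p = 0.0548), 2 (0.0538) or 3 (0.0537), P9 replicate 1 (0.0859), 2 (0.0828) or 3 (0.0846), or FFSS replicate 1 (0.0576) or 3 (0.113), and the YAP and SRF targets lower in P9 numbered 1 without P3 replicate 1, 2 or 3, P9 replicate 1, 2 or 3 or FFSS replicate 3. The cartilage genes higher in P9 numbered 2 without FFSS replicate 1. Synovial and tendon fibroblast markers were lower in P9 at 6 of 10 members and higher at 1, Tspan15, with the same counts adjusted over the list alone (set adjusted p = 0.00587; adjusted p = 0.0904 with an estimated correlation), and the set was not called without a filter. In P9 and FFSS they summed to 453 ± 95.4 and 2519 ± 371 FPKM (SD, n = 3).

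Single genes with the largest differences were higher in P9 for Osr1 (5.65), Il1rl1, the interleukin-33 receptor (5.48), Cadm4 (5.48), Serpinb9 (5.22), Stmn2 (4.97) and Akap12 (4.68). They were lower in P9 for Serpina3n (-7.57), Slpi (-7.53), Mt2A, a metallothionein (-6.67), Fosb (-6.45), Cxcl1 (-6.25) and Lcn2 (-5.92, adjusted p = 0.0202; lost without P9 replicate 1 (adjusted p = 0.0578), 2 (0.0546) or 3 (0.0542), or FFSS replicate 3 (0.0743)). Mt2A stood at 23.04 ± 1.62 FPKM in P9 and 2470 ± 481 FPKM in FFSS (SD, n = 3; adjusted p = 3.09e-07). Cdkn2a was higher in P9 than in FFSS by 1.36 (adjusted p = 0.00151), and Lmnb1 by 2.27 (adjusted p = 0.00768). Limma called 2103 genes higher and 1997 lower in P9 than in FFSS (4100 of 13059, 31.4%), and 42.2% of genes had groups that did not overlap, against 10% by chance. The count was 2667 without FFSS replicate 3 and 2491 with only the P9 and FFSS libraries.

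The question of a common mechanism was put to the genes called in both models. Both models lowered Dio3, Dynap, Cyp4b1, Sp7, Igfbp4 and Etl4, and raised Car9, Kcnk2 and Dusp1. Dio3 stood at 22.6 ± 1.29 FPKM in P3, 1.21 ± 0.274 in P9 and 1.37 ± 1.2 in FFSS (SD, n = 3; log2 fold changes -3.42 and -3.44). Sp7 stood at 16.5 ± 2.0, 1.18 ± 1.39 and 2.904 ± 1.79 FPKM (-3.17 and -2.27), and Igfbp4, an IGF-binding protein, at 40.6 ± 11.5, 5.55 ± 2.7 and 9.31 ± 1.45 FPKM (-2.70 and -1.98). Kcnk2, a mechanically gated potassium channel, rose by 2.12 in P9 and 2.41 in FFSS, and Dusp1, a phosphatase of MAP kinases, by 1.67 and 2.01. Egr1, Il15 and Trib1 were called higher in both as well, but less firmly. In P9 the call of Egr1 was lost without P3 replicate 1 (adjusted p = 0.0607) or 2 (0.0605), or P9 replicate 1 (0.053) or 2 (0.0697). The call of Trib1 was lost there without P3 replicate 1 (adjusted p = 0.0719), 2 (0.099) or 3 (0.11), or P9 replicate 1 (0.101), 2 (0.103) or 3 (0.0655), and that of Il15 without P3 replicate 1 (adjusted p = 0.0912), 2 (0.0701) or 3 (0.0676), or P9 replicate 1 (0.0703), 2 (0.0888) or 3 (0.0632). In FFSS, Il15 lost its call without P3 replicate 1 (adjusted p = 0.106), 2 (0.0935) or 3 (0.0746), P9 replicate 2 (0.0531) or 3 (0.0525), or FFSS replicate 2 (0.0738) or 3 (0.109). The collagen genes Col1a1 and Col5a2 fell in both models. Col1a1 went from 9777 ± 504 FPKM in P3 to 4805 ± 307 in P9 and 4415 ± 593 in FFSS (adjusted p = 0.00391 and 0.00231). Slc7a5 of the unfolded protein and amino acid stress list also fell in both. The members of lists called in both models were chosen after their values were seen.

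In number, 119 genes rose in both models and 173 fell in both, against 79.9 and 60.5 for independent lists of these sizes, while 79 rose in P9 and fell in FFSS and 88 did the reverse, against 73.4 and 65.9. Both contrasts use the same 3 control libraries, which alone makes fold changes correlate. Fold changes correlated at r = 0.062 across genes, against 0.289 (range 0.243 to 0.322) in 100 simulated draws without effect that shared the control. Of genes, 54.3% had the same sign in both, against 59.4%. The draws lack the spread that effects add, so neither gap can be interpreted. The covariance, 0.0226, lay within the draws (0.0217, 0.0176 to 0.0248). The draws gave 0 genes called in both with the same sign, against 292, but hold almost no calls. Their 0 says nothing of an overlap between groups that each changed. Part of the excess over independent lists may come from the shared control libraries. Of the 459 genes called in both models, 230 also differed between P9 and FFSS, as did 63 of the 292 with the same sign. Among those called in opposite directions, Akap12 and Cadm4 rose in P9 and fell in FFSS (log2 fold changes 2.43 and -2.25, 3.60 and -1.88), as did Il1rl1, whose FFSS call was lost without P3 replicate 1 (adjusted p = 0.0539) or 2 (0.0655). Cxcl1 and Angptl4 fell in P9 and rose in FFSS, as did Dcn, decorin. The call of Dcn was lost in P9 without P3 replicate 1 (adjusted p = 0.133) or 3 (0.141), P9 replicate 1 (0.127), 2 (0.123) or 3 (0.0513), or FFSS replicate 3 (0.0638) and in FFSS without P3 replicate 1 (adjusted p = 0.0599) or 2 (0.0784), or FFSS replicate 3 (0.0704). The 292 genes became 95 without P3 replicate 1, 140 without P3 replicate 2, 111 without P3 replicate 3, 147 without P9 replicate 2, 177 without FFSS replicate 3 and 660 without FFSS replicate 1. The 167 with opposite signs became 55, 72, 75, 86, 87 and 485 in the same fits. The balance of shared rises and falls moved too. In both, 350 rose and 310 fell without FFSS replicate 1, 142 and 151 with library totals, and 90 and 209 with equal FPKM totals.

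**Figure D4:**
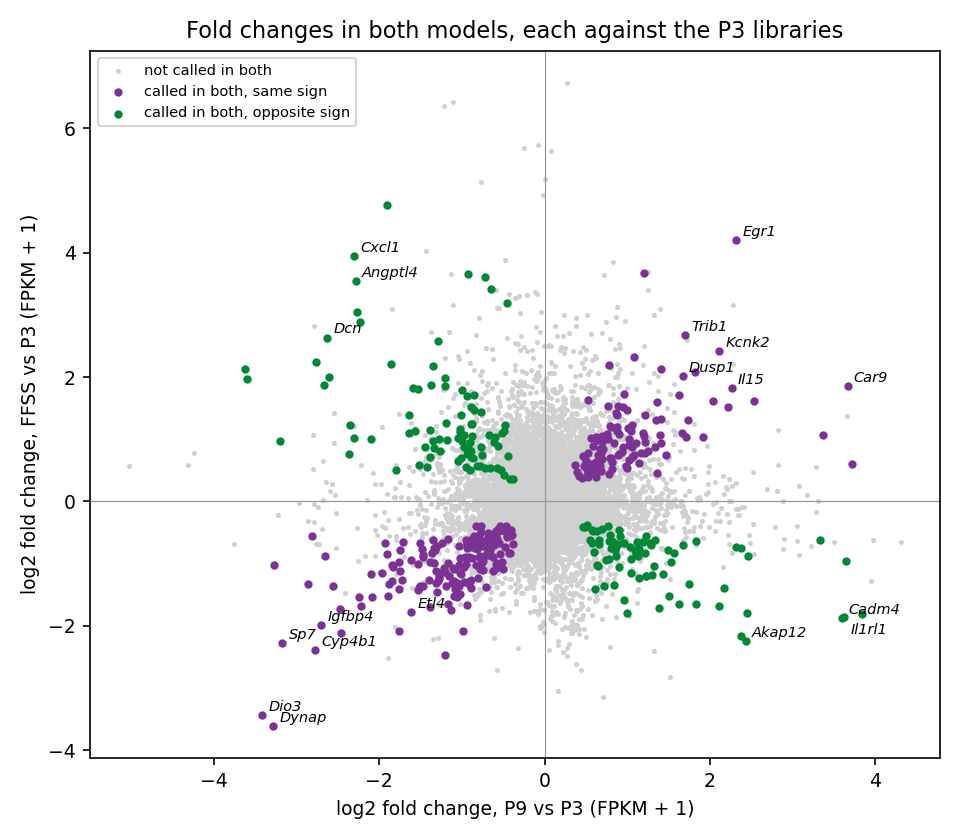
Each point is a tested gene, placed by its log2 fold change of FPKM + 1 in P9 vs P3 (horizontal axis) and in FFSS vs P3 (vertical axis). Purple points are the 292 genes called in both with the same sign, green points those called in both with opposite signs, and grey points all others; because the axes share the P3 libraries, chance alone tilts the cloud upward.

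The series title names a shortage of the microRNA miR-708-5p, which polyadenylated RNA does not measure in its mature form. The annotated Mir708 gene (ENSRNOG00000040447; Rnor_6.0 chromosome 1, 161221246 to 161221333, plus strand) had 3 fragments in P3 replicate 1 and 0 in the other 8 libraries, too few to test. Tenm4 (ENSRNOG00000011151; chromosome 1, 161401527 to 161880923, plus strand), a teneurin whose gene is known as the host of miR-708, lies downstream of Mir708 in this annotation rather than around it. Tenm4 fell in both models, from 1.997 ± 0.188 FPKM in P3 to 0.459 ± 0.0228 FPKM in P9 and 0.173 ± 0.105 FPKM in FFSS (SD, n = 3; log2 fold changes -1.04 and -1.36, adjusted p = 0.00432 and 0.00134). These values rest on 210 to 269 fragments per P3 library, 52 to 67 per P9 library and 9 to 36 per FFSS library. Tenm4 did not differ between P9 and FFSS by this test (log2 difference 0.32, adjusted p = 0.16). Whether messages with miR-708-5p sites changed was not tested, because no genome sequence of this build was at hand.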

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

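The tests chosen only after the result was seen were those of a fall in P9 hidden by the pooled spread, of dilution by cells without the flow response, of leukocytes lost by passage 9 and of fewer synovial or tendon fibroblasts. There were 5 lists that stood out because they were called in opposite directions in the models and differed between P9 and FFSS in the test of that difference. The secretory phenotype of senescent cells was lower in P9 and higher in FFSS, each against P3. P9 and FFSS differed with adjusted p = 4.85e-07 (0.0156 with an estimated correlation). NF-kB and Toll-like receptor signalling went the same ways, with adjusted p = 4.77e-14 for the difference (0.00739 with an estimated correlation). Matrix-degrading proteases did so with adjusted p = 0.000154 (0.0531 with an estimated correlation). Lysosome and autophagy genes did so with adjusted p = 1.06e-05 (0.0569 with an estimated correlation). DNA replication genes were higher in P9 and lower in FFSS, with adjusted p = 4.85e-07 (0.325 with an estimated correlation). Against P3, no P9 call of these lists held with an estimated correlation (adjusted p = 0.147 for secretory, NF-kB and protease genes, 0.250 for lysosome genes and 0.808 for replication genes). In FFSS the secretory (0.0232) and NF-kB (0.00611) calls held with it, and those of proteases (0.122), lysosome genes (0.145) and replication genes (0.443) did not. In P9, limma called 0 of 30 replication genes (5 at an unadjusted p under 0.05, 1 with voom), and the set's call (0.0456) was lost without P3 replicate 1 (0.0924), P3 replicate 3 (0.0560), P9 replicate 1 (0.0754) or P9 replicate 3 (0.0825). The protease and lysosome calls in P9 were lost without P9 replicate 3 (0.0597 and 0.0920).

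Mitosis genes were lower in FFSS (adjusted p = 1.97e-15; 0.294 with an estimated correlation) and not in P9, and this contrast may reflect a difference in proliferation between the models. The authors' scaling as the cause is argued against: the list's median in FFSS vs P3 was -1.84 with the deposited scaling and stayed at or below -1.831 when libraries were scaled by their totals or to equal summed FPKM (-1.93). A fall in P9 hidden by the pooled spread is argued against too, since 27 of 29 members had a higher mean in P9 than in P3, and 25 to 28 did with 1 P3 or P9 library left out. Other technical causes were not tested, and a biological difference stays as a hypothesis found and tested on the same data. Whether cell density or time in culture differed between the groups is not recorded and stays open.

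FFSS replicate 1 lay between P3 and the other FFSS libraries. A mislabelled P3 or P9 sample is argued against: of 3895 genes called in FFSS against both other groups without this library, it lay beyond all 6 P3 and P9 libraries in the called direction at 61.3%. Simple dilution by cells without the flow response would put every list at 1 position between P3 (0) and FFSS replicates 2 and 3 (1). The median positions were 0.633 for mitosis, 0.255 for immediate early and 0.827 for NF-kB genes, a difference of 0.572 (bootstrap SD 0.183 over genes). A weaker or differently timed exposure, unrecorded and untested, could give such positions, but interferon-stimulated genes summed highest in this library.

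The secretory, NF-kB and protease lists were called lower in P9 than in P3. All 3 calls were lost with an estimated correlation (adjusted p = 0.147 each), and that of proteases without P9 replicate 3 (0.0597). Loss of leukocytes by passage 9 stays open, since their markers summed to 0.680 FPKM more in P9 than in P3 but lie near the floor, with 1 of 20 past the filter, so that the sum cannot exclude it. Fewer synovial or tendon fibroblasts in P9 cannot be told apart from a change within the same cells: 7 of 10 markers had a lower mean in P9, 3 called lower and 1 higher, and the most abundant of them, Fmod, is also made by cartilage cells and belongs to the cartilage list. Passage itself stays among the open explanations, as untested.

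The 6 libraries of a pair of groups split 3 against 3 in 10 ways, too few for a share under 0.05. The real split always called the most genes (1 of 10 as large), 1284 in P9 vs P3 against 2 in the highest other split. It called 2845 against 1 in FFSS vs P3 and 4100 against 1 in P9 vs FFSS. For lists it called 12 against 10 in P9 vs P3 and 18 against 15 in P9 vs FFSS. These splits too were too few. In FFSS vs P3 another split called 15 against the real 13 (3 as large), so this count does not set the groups apart. For the 292 genes called in both models with the same sign, 4 of 100 regroupings of the 9 libraries into 3 groups of 3 gave as many, the real one included. The other 3 gave 1181, 1175 and 1073 genes, each with the 3 FFSS libraries as the shared control and P3 and P9 libraries mixed in the other groups, and the next highest gave 9. This points to a structure of the samples, in which FFSS libraries lie apart from P3 and P9. The count therefore does not test whether a response is shared, and chance is not excluded by it.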

How the results depend on the processing

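Chosen only after the data were seen were voom on recovered fragments and equal FPKM totals; the other alternatives were planned. No named gene past the threshold and no called list changed direction under any alternative run. Genes that were not called could change sign, as Cdkn1a did in P9 vs FFSS (-0.83 to 0.20 over libraries left out). A log2 fold change of at least 1 left 647 genes in P9 vs P3, 1042 in FFSS vs P3, 1723 in P9 vs FFSS, 89 shared with the same sign and 51 with opposite signs, by construction a subset of the calls. With only the libraries compared, 2488 genes were called in P9 vs P3 and 2491 in P9 vs FFSS. The first leaves out the FFSS libraries, which vary most, and the second has fewer libraries to set the spread. Without a filter, 104 genes were shared with opposite signs, over 21968 genes tested. With a filter of at least 5 FPKM, 6 lists were called in P9 vs P3 in place of 12, with fewer members tested, and the calls of secretory genes, proteases, lysosome genes, p53 targets, osteogenic genes and DNA replication were lost; otherwise the cause was not tested. Leaving out each library in turn gave 619 to 2230 genes in P9 vs P3 (lowest without P3 replicate 1, highest without FFSS replicate 1) and 1182 to 5131 in FFSS vs P3 (the same libraries). It gave 2667 (without FFSS replicate 3) to 5986 (without FFSS replicate 1) in P9 vs FFSS. Genes shared with the same sign ran from 95 to 660 and those with opposite signs from 55 to 485 (lowest without P3 replicate 1, highest without FFSS replicate 1). Where a group was left with 2 libraries, its spread was taken from all groups.

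To check pairing, residual correlations of same-numbered libraries of different groups were compared with those of other pairs. They ran from -0.041 to 0.033, within the -0.065 to 0.061 of differently numbered libraries, so the numbers gave no sign of pairing. With the replicate number as a block, 982, 2265 and 3629 genes were called in P9 vs P3, FFSS vs P3 and P9 vs FFSS, and 204 and 113 were shared with the same and opposite signs. Library totals alone gave 1313, 2784 and 4118 genes. Voom on the recovered fragments, of which 100% were whole within 0.01, gave 1295, 2825 and 4072. Equal FPKM totals gave 3079 genes in FFSS vs P3 (36.4% of them higher, against 52.1%) and 4309 in P9 vs FFSS (63.4% higher, against 51.3%) with the median of all genes at -0.116 and 0.106. Changes there are relative to those medians. Of 43 list calls, 6 passed with an estimated correlation and 37 with fry. Of the same 43, 35 passed with the filter of at least 5 FPKM, 38 without a filter and all 43 with the block and with equal FPKM totals. Over libraries left out in turn, 372 of 387 list values and 3222 of 3519 named-gene values stayed on their side of the threshold, while 263 of the latter were no longer past it and 34 newly past it. The negative-binomial tools and the median-of-ratios factors planned for counts were not run, the first because FPKM are not counts and the second because the deposited values already carry that scaling. The miR-708-5p site test was not run for lack of a genome. Depth limits genes near the filter: 1 fragment at 1 kilobase is 0.0619 to 0.0733 FPKM, and in simulated data 6.1% of 1.5-fold changes were recovered.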

Other observations

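All sets of genes described in this part were fixed in advance, and the single genes were chosen only after their values were seen; no test was added. In P9 vs FFSS, further lists differed. DNA replication genes were higher in P9 at 21 and lower at 1, Cdt1, of 30 members, 25 and 1 adjusted over the list alone (set adjusted p = 4.85e-07; adjusted p = 0.325 with an estimated correlation), with Ccne1 at 1.19 and Tyms, thymidylate synthase, at 1.78 on the log2 scale. The replication genes higher in P9 numbered 10 without P9 replicate 1, and 12 without P9 replicate 2 or FFSS replicate 3. Cdt1 lost its call without P9 replicate 2 (adjusted p = 0.0523). Chromatin and lamina genes were higher at 8 of 12 members, over all genes and adjusted over the list alone (0.000535; adjusted p = 0.218 with an estimated correlation), with Ezh2 of the Polycomb complex at 1.63. Lysosome and autophagy genes were lower in P9 at 15 and higher at 1, Atg7, of 36 members, 18 and 1 adjusted over the list alone (1.06e-05; adjusted p = 0.0569 with an estimated correlation), with Ctsd at -1.20 and Lamp1 at -0.79. Atg7 lost its call without P9 replicate 2 (adjusted p = 0.0663) or 3 (0.0656), or FFSS replicate 2 (0.0533) or 3 (0.0688). Interferon-stimulated genes were lower at 10 of 21, over all genes and adjusted over the list alone (0.000192; adjusted p = 0.218 with an estimated correlation). Unfolded protein and amino acid stress genes were lower at 17 and higher at 3, Psat1, Asns and Phgdh, of 30, with the same counts adjusted over the list alone (0.000643; adjusted p = 0.0914 with an estimated correlation). The falls numbered 10 without FFSS replicate 3, and Phgdh lost its call without P9 replicate 2 (adjusted p = 0.0884) or 3 (0.0814), or FFSS replicate 2 (0.0684) or 3 (0.0678). Adipogenic genes were lower at 6 of 9 (0.00645; adjusted p = 0.109 with an estimated correlation), a set not called without a filter. Hypoxia and glycolysis genes were lower at 11 of 30 and higher at 1, Car9 (0.00743; adjusted p = 0.0707 with an estimated correlation). They numbered 6 without FFSS replicate 3 for those lower and 5 without FFSS replicate 1 for those higher. Cholesterol synthesis genes were lower at 6 of 22 (0.00244, 0.0571 without P9 replicate 3; adjusted p = 0.529 with an estimated correlation), and the set was not called with fry. The cholesterol genes lower in P9 numbered 3 without P9 replicate 3 or FFSS replicate 3. Hypertrophic and osteogenic genes were lower at 5 and higher at 2, Dlx5 and Mef2c, of 12 (0.0495; adjusted p = 0.410 with an estimated correlation), a call lost without FFSS replicate 2 (0.109), FFSS replicate 3 (0.0585), P3 replicate 2 (0.0513), P9 replicate 1 (0.0927) or P9 replicate 2 (0.0891). It was also lost without a filter, with a filter of at least 5 FPKM, with only the libraries compared and with voom. The osteogenic genes lower in P9 numbered 8 without FFSS replicate 1.

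Progenitor markers moved both ways, and with all 9 libraries camera did not call the set. In P9, Mcam rose (1.30, adjusted p = 0.0071) and Grem1, a BMP antagonist, fell (-0.94, 0.00309), and the set of 21 had adjusted p = 0.0607. That set was called lower without FFSS replicate 1 (adjusted p = 0.0359) or FFSS replicate 2 (0.0387). In FFSS, Cspg4, the proteoglycan NG2 of pericytes, fell from 77.02 ± 2.94 to 24.1 ± 2.51 FPKM (SD, n = 3; adjusted p = 8.45e-05) and Pdgfra rose from 15.3 ± 2.35 to 35.95 ± 9.72 FPKM (0.00647), with a set adjusted p of 0.914. The 31 TGF-beta and BMP genes were not called as a set in FFSS (0.689) or P9 (0.544). Fst, follistatin, rose in FFSS from 12.2 ± 1.09 to 77.6 ± 30.7 FPKM (0.001), and Id3, a target of BMP signalling, rose in P9 by 1.24 (0.00191). The 24 Wnt genes were not called as a set in FFSS (0.836) or P9 (0.153), with Lef1 at -1.38 in FFSS (0.00133) and Ccn5 at -1.65 in P9 (0.00245). Of 9 adipogenic genes, Plin2 of lipid droplets rose in P9 (0.87, 0.00643) and in FFSS (1.42, 0.000787), with set adjusted p of 0.198 and 0.218.

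Other lists were not called with all 9 libraries. In P9 vs P3 they were oxidative phosphorylation (adjusted p = 0.0605), synovial and tendon fibroblast markers (0.0723), cholesterol synthesis (0.0984), hypoxia and glycolysis (0.3), NRF2 and antioxidant genes (0.354), heat shock genes (0.521), interferon-stimulated genes (0.630), chromatin and lamina genes (0.754), immediate early genes (0.772) and cell cycle arrest genes (0.902). Limma called 0 of 22 cholesterol genes (0 at an unadjusted p under 0.05), 0 of 21 interferon genes (1), 0 of 17 heat shock genes (2) and 0 of 12 chromatin and lamina genes (1), and voom called 0 in each. Without FFSS replicate 1, 2 heat shock genes and 1 chromatin gene were called higher and 1 interferon gene lower; without FFSS replicate 2, 1 heat shock gene higher. In FFSS vs P3 they were contractile genes (0.0585), cartilage genes (0.0636), synovial and tendon fibroblast markers (0.0793), unfolded protein and amino acid stress genes (0.233), heat shock genes (0.328), fibrillar collagens and fibrous matrix (0.360), cell cycle arrest genes (0.527), hypertrophic and osteogenic genes (0.543), YAP and SRF targets (0.543) and oxidative phosphorylation (0.689). In P9 vs FFSS they were NRF2 and antioxidant genes (0.0653), progenitor markers (0.132), fibrillar collagens and fibrous matrix (0.273), Wnt genes, p53 targets, TGF-beta and BMP genes and oxidative phosphorylation (0.288 each), and heat shock and cell cycle arrest genes (0.566 each). Some were called with 1 library left out. In P9 vs P3 these were oxidative phosphorylation without P3 replicate 3 (adjusted p = 0.0127), P9 replicate 1 (0.00439) or P9 replicate 3 (0.0446), fibroblast markers without P3 replicate 2 (0.0427) or P9 replicate 3 (0.0393), and cholesterol synthesis without P3 replicate 2 (0.000354), P9 replicate 1 (0.0201) or P9 replicate 2 (0.0271). In FFSS vs P3 they were contractile genes without P3 replicate 3 (0.011) or FFSS replicate 2 (0.0471), cartilage genes without P3 replicate 3 (0.0422) or P9 replicate 3 (0.0374), and fibroblast markers without P9 replicate 3 (0.0483). In P9 vs FFSS they were antioxidant genes without P9 replicate 3 (0.0218), and p53 targets (0.00952) and oxidative phosphorylation (0.0445) without FFSS replicate 1. Median, mean and test differed in sign for some of these. In P9 vs P3, immediate early genes had a median of 0.15 and a mean of 0.10 with a test direction of lower, and NRF2 genes a median of 0.01 and a mean of -0.01 with a direction of higher. In FFSS vs P3, TGF-beta and BMP genes had a median of -0.08 and a mean of 0.13, Wnt genes -0.07 and 0.11, and progenitor markers -0.06 and -0.01, each with a direction of higher.

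Markers of other cell types were also summed, and which cells made them was not tested. Endothelial markers summed to 14.9 ± 0.340 FPKM in P3, 16.9 ± 2.95 in P9 and 19.8 ± 2.55 in FFSS (SD, n = 3), epithelial markers to 3.74 ± 1.89, 4.77 ± 0.810 and 9.45 ± 3.46, erythroid markers to 0.770 ± 0.320, 0.550 ± 0.370 and 0.350 ± 0.370, and glial and Schwann cell markers to 93.3 ± 13.9, 56.4 ± 6.88 and 165 ± 19.4, of which Pmp22 and S100b gave most. Skeletal muscle markers summed to 27.9 ± 15.6 FPKM in FFSS (SD, n = 3).

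A pair of adjacent protein-coding genes without a common symbol, AC128059.1 and AC128059.4 (Rnor_6.0 chromosome 8, 116776494 to 116779156 and 116771982 to 116773868, plus strand), were seen almost only under shear: 10.2, 164 and 95.3 FPKM and 6.26, 79.5 and 65.9 FPKM in FFSS replicates 1 to 3, with at most 0.370 FPKM in any other library. A snoRNA annotation, RF00560 (chromosome 6, 128084033 to 128084163), had 12, 172 and 143 fragments in FFSS replicates 1 to 3 and 0 in the other libraries; it lies just past the end of Serpina3n (127941526 to 128080889), which had 5612, 52178 and 34147 fragments in the same libraries. Ndufa1 had 495 fragments in P3 replicate 3 and at most 7 in any other library.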
